A study of Homo sapiens with 8 samples.

How the data were processed

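E4F1 ChIP and input DNA were sequenced from SUM159 cells, untreated or treated with 140 nM gemcitabine for 24 h, with 2 replicates in each of 4 groups. Libraries were made with a TruSeq ChIP kit and sequenced on an Illumina HiSeq instrument, per the labels' protocols. The submitters' processing notes name bcl2fastq, FastQC, Bowtie2, HOMER, deepTools and the build hg38. Their versions, and how duplicate or multiply mapping reads were treated, are not given in the sources used here. Peaks were called with HOMER findPeaks in its transcription factor mode on ChIP tags combined over replicates A and C, against the combined input, per the file headers. The limits were a false discovery rate of 0.001, 4-fold over input, 4-fold over the surrounding 10 kb and a Poisson p of 1e-04. The headers also give a lowest score of 30 and at most 6 tags per bp. Pooling replicates before calling means that a peak can rest on 1 replicate, and libraries for each replicate were not analysed here.

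Of 11050 untreated and 10729 gemcitabine putative peaks, the input limit removed 10877 (98.4%) and 10431 (97.2%) and the local limit 57 and 43, per the file headers. The final lists are thus those sites that passed fixed limits over input and over the local region.

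Each deposited list gives several kinds of value per peak. Tag counts per peak are deposited with one library unscaled and the other scaled down to the shallower depth as a signal: ChIP tags were scaled to the input in the untreated list, and input tags to the ChIP in the gemcitabine list, per the file headers. The unscaled counts were recovered by dividing by a scale of 0.93282 for untreated and 0.88798 for gemcitabine, and 100% and 99.6% of recovered values were whole numbers within a tolerance of 0.1. These scales put the input depth at about 117100000 and 136900000 tags. The score is the authors' peak height in position-adjusted tags. Ratio columns, the fold over input and over the local region, were deposited as the caller gave them, and the fraction called focus ratio is the deposited share of tags on the side of the centre where a point source would place them. The p-value columns are the authors' Poisson values against input. Gene names, annotation classes and distances to the TSS were those deposited from HOMER annotatePeaks with hg38, per the file headers. The deposited BED copies were checked to hold the same peaks. There were 0 columns of single samples in the files.

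From there, peaks were called shared when they overlapped by at least 1 bp (bedtools 2.31.1). Shares have exact Clopper-Pearson intervals at 95% confidence. Scores of shared and list-specific peaks were compared within each list by 2-sided permutation tests of the difference in median log2 score (100000 resamples), and promoter shares by 2-sided Fisher's exact tests. ChIP tag ratios at shared peaks used total ChIP tags as the denominator (printed per 10000000 tags), with exact conditional binomial intervals. With 1 pooled list per condition there was no replicate error, and no test of the conditions was made; tests and intervals that set the lists side by side compare the pooled libraries. The windows in which tags were counted were 161 bp in the untreated and 167 bp in the gemcitabine list.

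Genes were taken as bound when a peak centre on chromosomes 1 to 22, X or Y lay within 1000 bp of the canonical TSS of a protein-coding gene in the GENCODE annotation of hg38 (20007 genes), whose chromosome names and lengths were checked against the peak coordinates. The 15 gene lists came from textbook gene families and from published work on E4F1, so the checkpoint, PIKK and pyruvate dehydrogenase lists are not independent of what is known of this factor. Some lists took their members by a pattern in the gene symbol, so membership there follows gene names and not a known function. The consensus site was searched on both strands of the reference. A planned split of peaks by this site was not made, because 1 of 255 gemcitabine and 0 of 116 untreated peaks held it. Near-identical copies (at least 95% identity over at least 90% of the peak) were searched with blastn 2.17.0 and found for 3 of 116 untreated and 5 of 255 gemcitabine peaks.

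The text names the 25 shared peaks with the highest untreated score, the 20 gemcitabine-specific and the 10 untreated-specific peaks with the highest score in their list, the members of the gene lists with a peak, and E4F1, CDKN1A and CHEK1. Some items that the rule or the gene lists cover are not reported here. This rule, the tests, the gene lists and the first set of alternatives were fixed before the data were examined. Peaks on other contigs are named by contig. Alternatives covered the overlap rule, the fold limits, the list length, the promoter distance, the scaling of tags, the contigs, and the width and mismatches of the site search. Those added later were the nearest gene of the authors' annotation, a CpG-rich background, subtraction of expected background tags, further restrictions to the main chromosomes, the site search in peaks of at least 8-fold, and the removal of peaks with near-identical copies.

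Scripts ran in python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9. They were tested on simulated data before use. All of 98 planted overlaps and 80 of 80 planted sites were found. A planted gene list of 10 members was called in 100 of 100 sets, and random sets gave a call in 16 of 300. The permutation test called 100 of 100 planted shifts of 1 log2 unit and 3 of 100 unshifted sets.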

Results

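SUM159 is an established line of triple-negative breast cancer cells, which lack the estrogen and progesterone receptors and amplified HER2. Binding of E4F1, a zinc-finger transcription factor and ubiquitin ligase that acts in cell cycle control, checkpoint signalling and mitochondrial metabolism, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq). Cells were either untreated or exposed for 24 h to 140 nM gemcitabine, a nucleoside analog that blocks DNA synthesis, at the dose the labels call the 30% inhibitory concentration. The 8 libraries formed 4 groups of 2 replicates each, an E4F1 ChIP and an input DNA for each condition. Replicates were labelled A and C, and the labels did not say whether they came from separate cultures. The peak lists pooled both replicates, so 1 list stood for each condition and no value below has a replicate error. The pooled ChIP libraries held 125564020 tags (mapped sequencing reads) in untreated cells and 121607452 tags in gemcitabine-treated cells. Coordinates are hg38 throughout.

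The first question was where E4F1 bound in each condition. In untreated cells E4F1 lay mostly at promoters: 102 of 116 peaks (87.9%, exact 95% interval 80.6 to 93.2) had their centre within 1000 bp of the nearest annotated transcription start site (TSS). In gemcitabine-treated cells 234 of 255 peaks (91.8%, exact 95% interval 87.7 to 94.8) did. The binding was close to the start itself, with 75% of untreated and 73.7% of gemcitabine peaks within 100 bp of a TSS. By the authors' annotation, 94 untreated peaks lay at a promoter or TSS, 7 in a 5′ UTR, 4 in introns and 10 between genes. The gemcitabine list held 213, 17, 4 and 14 of these classes, with 4 more in non-coding transcripts and 2 in exons, and 1 peak of each list had no class. The 234 peaks near a TSS and the 213 at a promoter or TSS include a peak on the mitochondrial genome, described further on.

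The highest-scoring peaks that both lists contained belonged to genes of RNA processing, transcription, translation and ribosome assembly. The first of them by untreated score was UTP25, a ribosome biogenesis factor, with a peak on chromosome 1 from 209827849 to 209828009, at -38 bp from its TSS, and a score of 179 (178 ChIP tags against 15 input tags). MRFAP1 followed, with a peak in the 5′ UTR of exon 1 on chromosome 4 from 6640564 to 6640724 and a score of 177. The spliceosome-associated CTNNBL1 scored 165, and LEO1, a subunit of the PAF1 elongation complex, and NEURL4 each scored 160. Also among the first 25 were GNL3, NARFL, ASB7, GGCX, NCOA5, TAF5 (a TFIID subunit), NUDT9, ZMAT2, ZNHIT6, CLEC16A, MRFAP1L1, DPH5, CACUL1, CNOT11, ZNF862, the elongation factor EEF1G and the tRNA synthetase EPRS. Scores and folds are the values the authors' peak caller gave each peak, and they serve here to rank and describe peaks within a list.

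CHEK1, the kinase of the S and G2 checkpoints, was bound in both lists. Its peak on chromosome 11, from 125625831 to 125625991 in untreated cells, lay in the promoter, at -313 bp from the annotated TSS, with a fold over input of 9.72, and its gemcitabine peak had a fold of 13.67. E4F1 had a peak at its own gene in both lists, in the 5′ UTR of exon 1, on chromosome 16 from 2223518 to 2223678 in untreated cells, with 104 ChIP tags against 20 input tags. The gemcitabine peak at E4F1 held 156 ChIP tags. No peak lay within 1000 bp of the TSS of CDKN1A, a cyclin-dependent kinase inhibitor, in either list. A missing call means that no site passed the caller's limits at this depth and enrichment.

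The second comparison asked which peaks the conditions had in common. Of the untreated peaks, 98 of 116 (84.5%, exact 95% interval 76.6 to 90.5) overlapped a gemcitabine peak by at least 1 bp, and these made up 38.4% of the gemcitabine list (exact 95% interval 32.4 to 44.7). The gemcitabine list held 157 further peaks. By score, those on numbered chromosomes began with CEP290, a ciliary protein (score 174, chromosome 12 from 88142073 to 88142239), GOLGA7 (158, chromosome 8 from 41490443 to 41490609) and NDUFS5, a subunit of respiratory complex I (150, chromosome 1 from 39026218 to 39026384). NAA30, CWF19L2, DMAP1, IPO8, KIF1BP, NOL6, NDUFS7, HAX1, ZC3H10, TBC1D23, EIF1AD, INTS12, EIF3K, AP3S2, SMG8 and IPO4 came next, with scores from 146 to 84. All of the named peaks from CEP290 to IPO4 lay within 1000 bp of a TSS.

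The untreated list held 18 peaks of its own, with scores from 30 to 45. They were led by TUT1, MTERF4 and TMEM41A at promoters, and by an intergenic site 103403 bp from MTRR that lay in an endogenous retroviral repeat. Another promoter peak lay at -591 bp from the TSS of SRD5A3-AS1, and the other named ones were distal sites nearest to FRG1CP, FZD1, THEM5, FAM230C and MBOAT1. The FAM230C site lay in alpha satellite and had 3094 near-identical copies elsewhere in the genome. At a fold over input of at least 8 in both lists, 36 peaks were shared, 3 were untreated-specific and 75 were gemcitabine-specific. With the gemcitabine list limited to its 116 highest scores, 33 peaks were specific to each list, counts that equal list lengths make equal by construction.

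Within each list, shared peaks scored higher than the rest. The untreated medians were 87.5 for shared and 31 for untreated-specific peaks, a log2 difference of 1.50, and the gemcitabine medians were 140.5 and 53, a log2 difference of 1.41. Both 2-sided permutation tests across peaks gave p = 1e-05, the smallest value that 100000 resamples allow (adjusted p = 1e-05 over 2 tests). With the fold over input in place of the score, the log2 differences were 0.40 (permutation p = 0.0235) and 1.20 (permutation p = 1e-05). All of the 75 highest-scoring untreated peaks and all of the 25 highest-scoring gemcitabine peaks on chromosomes 1 to 22, X and Y were shared. Peaks specific to the gemcitabine list ranged in score from 30 to 174 on these chromosomes, and 65 of 157 scored under 50. These tests ran across peaks, not across replicates. Shared peaks had to pass the same limits in the other list, so the direction of these differences was largely set by how the sets were defined.

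**Figure D1:**
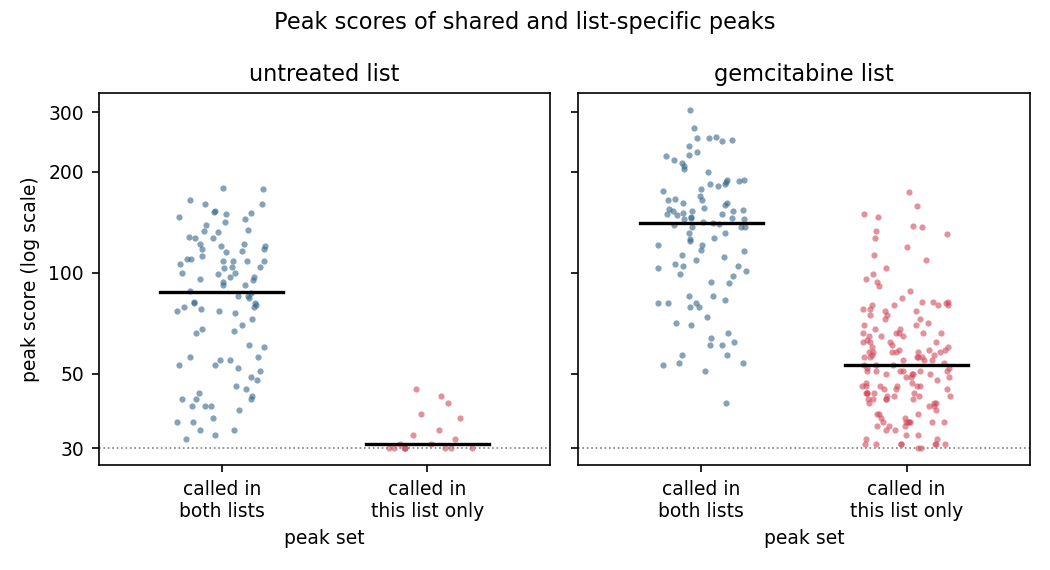
Peak score on a log axis for each peak of the untreated list (left) and the gemcitabine list (right), split into peaks called in both lists and in that list only; each point is a peak, black bars are medians, the dotted line is the score limit of 30, and the mitochondrial peak is left out. The 18 untreated-specific peaks sit between 30 and 45, while the gemcitabine-specific peaks reach 174.

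Promoters held 97 of the 98 shared peaks (99.0%, exact 95% interval from 94.4 upward). They held 137 of 157 gemcitabine-specific peaks (87.3%, interval 81.0 to 92.0) and 5 of 18 untreated-specific peaks (27.8%, interval 9.69 to 53.5). The 137 include the mitochondrial peak. Of the untreated-specific peaks, 10 were intergenic, 4 intronic, and 7 were annotated to a repeat. Fisher's exact test across peaks gave adjusted p = 0.000635 for shared against gemcitabine-specific peaks and adjusted p = 4.16e-12 for shared against untreated-specific peaks. At a fold over input of at least 8, the first difference shrank from 11.7 to 4.00 percentage points (Fisher's exact p = 0.550).

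The third comparison set ChIP tags at the 98 shared peaks side by side. Relative to total ChIP tags, the gemcitabine library had more tags than the untreated library at 98 of 98 shared peaks, with a median ratio of 1.62 (quartiles 1.45 and 1.76). The fold over input was higher in gemcitabine at 89 of the 98. A site had to pass the limits in both lists to be shared, so sites with fewer gemcitabine tags could drop out of this set. The largest ratios were at TOP3B, a topoisomerase (2.53, 95% interval 1.75 to 3.72), VPS51 (2.51, interval 1.73 to 3.68), COPS7B (2.29, interval 1.65 to 3.23) and TAF5 (2.23, interval 1.82 to 2.75), chosen after their values were seen. The smallest were at CDK8, a Mediator kinase (1.05, interval 0.788 to 1.41), DUS1L (1.09, interval 0.683 to 1.73) and MKRN3 (1.12, interval 0.735 to 1.72). UTP25 went from 14.2 to 21.9 tags per 10000000 (ratio 1.54, interval 1.27 to 1.88) and CHEK1 from 9.96 to 14.0 (ratio 1.40, interval 1.11 to 1.78). At DLAT, the acetyltransferase subunit of the pyruvate dehydrogenase complex, the ratio was 1.99 (interval 1.36 to 2.95).

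Summed over the shared peaks, the ratio was 1.61 (exact 95% interval 1.57 to 1.65), and the interval of a single peak lay above 1 at 90 of the 98. Single-peak intervals excluded the overall ratio at 6 peaks, 4 above it and 2 below, where 4.9 are expected by chance. The input libraries, counted in the same way, gave 0.910 (interval 0.839 to 0.988). These intervals cover counting error only, and they take each tag as an independent molecule. Sequenced PCR copies are not independent molecules, so the intervals may be too narrow even for that error. The ratios compare pooled libraries, not conditions. Scaled to the tags in shared peaks in place of all tags, the median log2 ratio went from 0.70 to 0.012, which this scaling puts near 0 by construction.

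**Figure D2:**
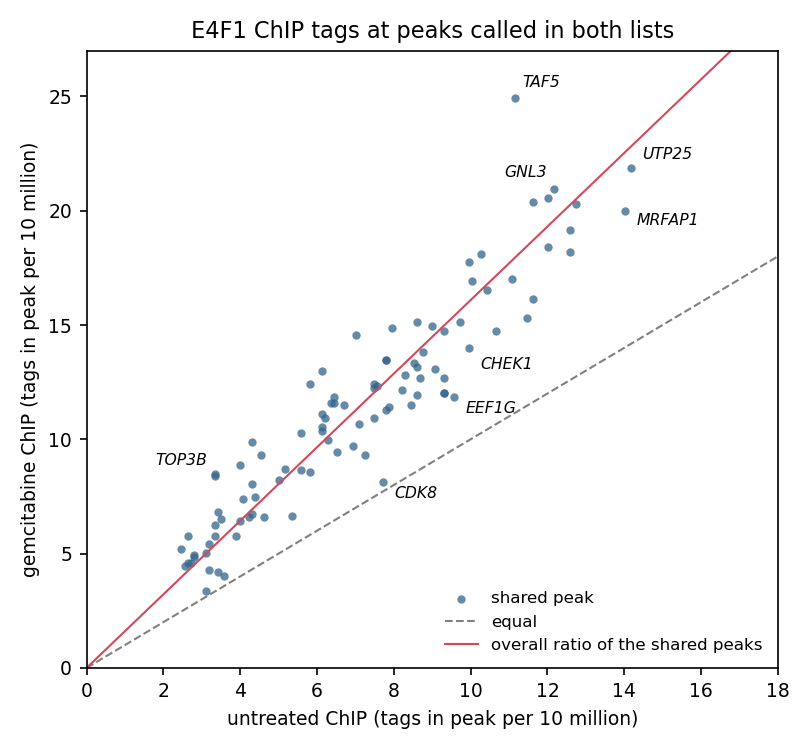
ChIP tags per 10000000 total tags in untreated (horizontal axis) and gemcitabine-treated (vertical axis) cells at the 98 shared peaks, each point a peak; the dashed line marks equal values and the red line the overall ratio of 1.61. All 98 points lie above the dashed line when scaled to total tags.

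The fourth comparison asked which groups of genes E4F1 bound, using 15 gene lists fixed before the data were examined. The checkpoint, PIKK and pyruvate dehydrogenase lists drew on published work on E4F1, so a pass for them is no independent test. Some lists took members by gene symbol, so a named member need not act in the process that names its list. Promoter peaks within 1000 bp of the TSS were found at 121 of 20007 protein-coding genes in the untreated list and at 285 in the gemcitabine list, and 117 genes were in both. Mitochondrial import, mitochondrial ribosome and pyruvate dehydrogenase genes passed the test in both, and respiratory chain genes did not pass in the untreated list (2 of 116, adjusted exact p = 0.292). In the untreated list, peaks lay at 4 of 32 mitochondrial import genes (DNAJC19, TIMM23, TIMM23B and TOMM7; adjusted exact p = 0.000602), 4 of 78 mitochondrial ribosome genes (MRPL16, MRPL21, MRPL40 and MRPL44; adjusted exact p = 0.00964) and 2 of 19 genes of the pyruvate dehydrogenase group (DLAT and the mitochondrial pyruvate carrier subunit MPC1; adjusted exact p = 0.0290). The shared peaks gave these lists with the same members at an adjusted exact p of 0.000528, 0.00852 and 0.0272. All p-values of gene lists are from 1-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 15 lists per peak set.

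In the gemcitabine list 7 gene lists passed an adjusted p of 0.05. Peaks lay at 8 of 78 mitochondrial ribosome genes, MRPL15, MRPL58, MRPS18C and MRPS31 being the additional ones (adjusted exact p = 0.000228), and at 7 of 116 respiratory chain genes (COX4I1, NDUFAF1, NDUFB3, NDUFS3, NDUFS5, NDUFS7 and UQCC6; adjusted exact p = 0.00688). Of these 7, COX4I1 and NDUFS3 also had an untreated peak. The pyruvate dehydrogenase group had 3 members, with PDPR, the regulatory subunit of its phosphatase, added (adjusted exact p = 0.00878), and mitochondrial import had the same 4 genes (adjusted exact p = 0.00688).

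Outside mitochondria, peaks of the gemcitabine list lay at 6 of 109 translation factor and tRNA synthetase genes (EEF1G, EIF1AD, EIF3D, EIF3K, EIF4B and EPRS1; adjusted exact p = 0.0142) and at 5 of 87 splicing genes (LSM4, SF3A3, SF3B6, SNRPB and SNRPD3; adjusted exact p = 0.0202). They also lay at 2 of 13 genes of the PIKK kinases and their TTT and R2TP chaperones (MTOR and TTI2; adjusted exact p = 0.0305). In the untreated list these groups had 3, 0 and 1 members, with adjusted exact p = 0.0855, 1 and 0.190. At a fold over input of at least 8, the translation, splicing and PIKK groups did not pass in the gemcitabine list. Whether a group differed between the conditions was not tested. Against genes with CpG-rich promoters alone, a background chosen after seeing the data, 3 gene lists passed in the gemcitabine list. The respiratory chain, splicing and translation groups then had adjusted exact p = 0.0580 each and the PIKK group 0.379, and the pyruvate dehydrogenase group had 0.0550 untreated and 0.0513 for shared peaks.

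Checkpoint and DNA repair genes had 3 of 90 members with a peak in both lists, CHEK1, the recombination factor RAD52 and TTI2, a chaperone subunit for kinases such as ATM and ATR. This group did not pass the test (adjusted exact p = 0.0649 untreated, 0.229 gemcitabine). Proteasome genes had 1 untreated member, PSMB6, and 3 gemcitabine members with PSMF1 and PSMG3 (adjusted exact p = 0.421 and 0.0579). Cytosolic ribosome genes had RPS7 and RPS16 in both (adjusted exact p = 0.205 and 0.490). Genes of gemcitabine and nucleoside metabolism had no untreated peak and 1 gemcitabine peak, at NME1 (adjusted exact p = 1 and 0.490). The lists of DNA replication, cell cycle and mitosis, and autophagy and lysosome had 0 members with a peak in either list (adjusted exact p = 1 each).

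The mitochondrial import count carries a limit of its own. TIMM23 and TIMM23B share their peaks with PARGP1 and PARG, on chromosome 10 from 45972360 to 45972520 and from 49941927 to 49942087, which are copies of each other with 98.1% identity, so the copy a read came from is uncertain. Without peaks that have a near-identical copy, 2 import genes were left, with adjusted exact p = 0.0594 untreated and 0.138 gemcitabine, and the pyruvate dehydrogenase group, which lost PDPR, had adjusted exact p = 0.0633 in the gemcitabine list. At a fold over input of at least 8, the mitochondrial ribosome had adjusted exact p = 0.484 untreated and 0.0716 gemcitabine, the untreated pyruvate dehydrogenase group 0.157 and the gemcitabine respiratory chain 0.435.

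**Figure D3:**
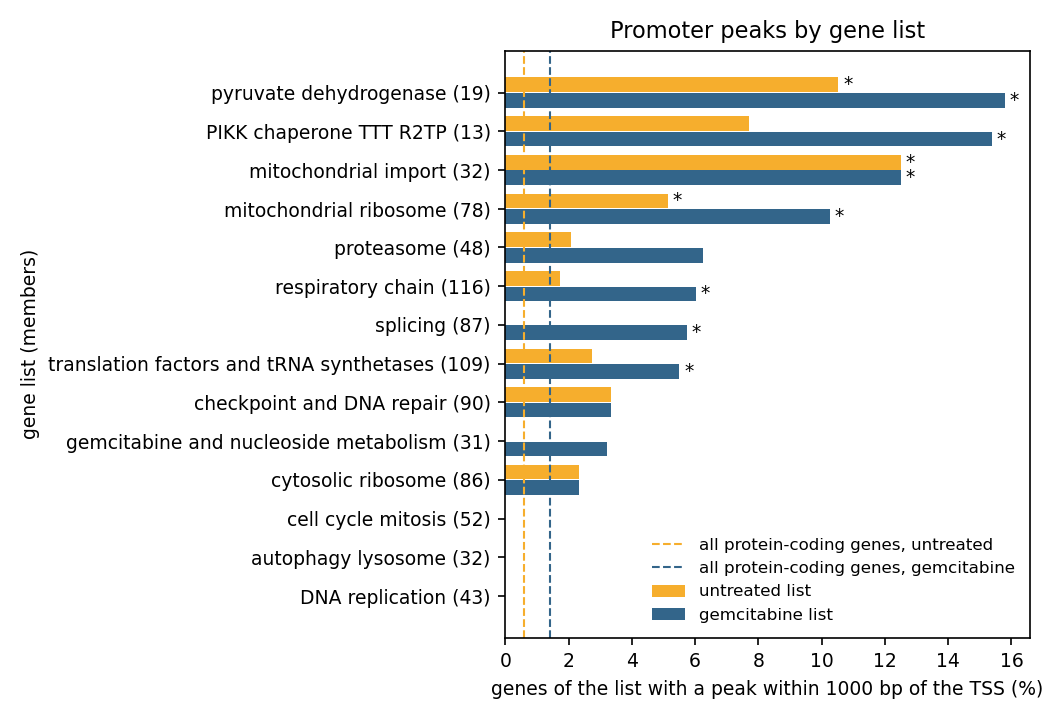
Percent of the genes in each gene list described in the text with a peak within 1000 bp of the TSS, in the untreated list (yellow bars) and the gemcitabine list (blue bars); list sizes are in parentheses, asterisks mark an adjusted p under 0.05, and dashed lines give the percent among all 20007 protein-coding genes (0.605 and 1.42). The pyruvate dehydrogenase group reaches 10.5% and 15.8%.

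The last comparison asked whether the peaks contain the published E4F consensus site, RTGACGTMAY (R is A or G, M is A or C, Y is C or T). The site was nearly absent at promoters bound by E4F1. It lay within 100 bp of the centre of 0 of 116 untreated peaks, which allows a share of up to 3.13% (exact 95% bound), and of 1 of 255 gemcitabine peaks (0.392%, interval 0.00993 to 2.17), at WFDC3 on chromosome 20 from 45791809 to 45791975. With 1 mismatch allowed, it lay in 3 untreated peaks (2.59%), at RALGAPA1, ZNF330 and E4F1 itself, and in 6 gemcitabine peaks (2.35%). Windows of the same width 1000 bp upstream and downstream held it at 1 and 5 untreated and at 8 and 10 gemcitabine sites, and exact McNemar tests gave p = 0.727 and 0.791, the larger p of both sides. The genes named here were chosen after their sites were seen.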

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

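The tests of the gemcitabine-specific peaks, of the tags at shared peaks and of the untreated-specific peaks were all chosen after those results were seen.

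A mitochondrial peak in the gemcitabine list, at positions 62 to 228 of the mitochondrial genome, lay outside the gene comparisons and above its input, with a fold of 4.38 and 13281 ChIP tags, 36.9% of all tags in gemcitabine peaks. A peak on the unplaced contig KI270752v1, of 27745 bp, was also above input in both lists, with a fold of 7.70 untreated. This peak is among the shared peaks used for the tag ratios, and its untreated call was annotated to an Alu repeat. Its folds over the local region were 4033 untreated and 1382 gemcitabine. In gemcitabine its input held 0 tags against 70 ChIP tags, so the caller's fold of 157.66 is not a measured one; over a floor of 3 input tags it was at least 26.3-fold higher.

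The gemcitabine list held 157 peaks of its own. Deeper ChIP sequencing is argued against by the totals, since the gemcitabine ChIP had 0.968 times the untreated tags. A fixed 4-fold limit applied to lists of different enrichment stays open: divided by the median fold ratio of shared peaks, 1.79, 74.5% of the 157 (exact 95% interval 67.0 to 81.1) fell under 4-fold, which a division by one factor cannot show to be the cause. For 27 of the 157 (17.2%), among them GOLGA7, NDUFS5, NAA30 and DMAP1, the divided fold stayed at 4 or more and the divided score at 30 or more. Gain of E4F1 at these sites under gemcitabine stays open too, because the lists pool replicates and the untreated tags at sites not called were not analysed here.

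ChIP tags were higher in gemcitabine at 98 of 98 shared peaks, a set of sites that had to be called in both lists. Wider windows are argued against, because the width ratio was 1.04. Whether a common factor between the pooled ChIP libraries could account for all of it cannot be told apart from differences between sites: the heterogeneity chi-square test of the 98 ratios gave p = 0.0499, and p = 0.0572 over the 97 peaks on the main chromosomes. Such a factor could be technical, such as the yield of the immunoprecipitation, or a general rise in E4F1 binding, and the pooled libraries leave both untested. The chi-square test also takes each tag as an independent molecule, so PCR copies could lower its p.

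Whether the 18 untreated-specific peaks are chance calls near the limit stays open. The sequence element GYCGYAAA, described further on, lay in 0 of the 18, which allows up to 18.5%, and in 15.3% of gemcitabine-specific peaks, the other set not used to choose it (Fisher's exact p = 0.139). A count of 0 is the lowest possible, so this test could not have passed 0.05 in that direction. No biological explanation was tested for them.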

How the results depend on the processing

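The main results of the report were each recomputed under the alternatives set out for them, not under all; the tests of explanations, the element GYCGYAAA and the divergent promoters were not. Of the alternatives, the nearest-gene rule, the CpG-rich background, the removal of copied peaks, the background subtraction and some restrictions to the main chromosomes were chosen after seeing the data. Of 174 recomputed values, 136 kept their direction and their side of the threshold or moved little, 17 moved, 19 lost significance and 2 reversed. With a fold over input of at least 8, the lists held 39 untreated and 111 gemcitabine peaks, 97.3% of the latter at promoters, with 36 shared, 3 untreated-specific and 75 gemcitabine-specific. The promoter difference between shared and gemcitabine-specific peaks was then 4.00 percentage points, and the gene lists past 0.05 numbered 1 untreated, 2 gemcitabine and 1 shared (from 3, 7 and 3). The splicing and PIKK lists, at 5 and 2 members in the gemcitabine list, then had 0 and 0. Gemcitabine folds of the 5 splicing members ran from 4.02 (SNRPD3) to 5.63 (LSM4), and MTOR and TTI2 had 4.75 and 7.82. The translation group had adjusted exact p = 0.435, and the shared mitochondrial ribosome and pyruvate dehydrogenase groups 0.484 and 0.157. With a fold over the local region of at least 8, 1 untreated-specific and 83 gemcitabine-specific peaks remained. With the longer list limited to its 116 highest scores, 33 peaks were untreated-specific and 33 gemcitabine-specific. With tags scaled to their sum over shared peaks, the median log2 ratio was 0.012, by construction near 0. With the nearest gene of the authors' annotation, 5 lists passed untreated, 5 for shared peaks and 6 in the gemcitabine list, where mitochondrial import fell to 2 members (adjusted exact p = 0.103), and against CpG-rich promoters 3 passed in the gemcitabine list; the cause was not tested. With peaks that have a copy removed, shared mitochondrial import had 2 members (adjusted exact p = 0.0542). With the fold in place of the score, the log2 difference of untreated medians was 0.40 (permutation p = 0.0235). The overlap rule, the promoter distance and the site search changed no call. No paired analysis was possible because each list pools replicates A and C, and for the same reason no replicate could be left out. Low counts limit single peaks, which hold from 26 untreated and 28 gemcitabine ChIP tags upward. Enrichment was low too: peaks on the main chromosomes held 0.00734% of untreated and 0.0186% of gemcitabine ChIP tags.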

Other observations

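The search for the element GYCGYAAA was chosen after words of 8 bases were seen to recur in the shared peaks, and the share in shared peaks is therefore no test. The tests in gemcitabine-specific peaks, in unbound promoters and of divergent promoters were set out before their results were seen.

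E4F1-bound promoters were often divergent, with 2 genes transcribed away from each other from starts at most 1000 bp apart. Of 239 bound promoter regions with a CpG-rich start, 42 (17.6%) were divergent, against 841 of 12473 others (6.74%), an odds ratio of 2.95 (Fisher's exact p = 1.91e-08). A divergent region has 2 starts near which a peak can lie, which may add to this value, and that was not tested.

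Although the published consensus was nearly absent, the shared peaks had a common sequence. Words of 8 bases within 50 bp of the centre of the 98 shared peaks were ranked. The rank was by the count there less the mean count in windows 1000 bp to either side. GCCGTAAA came first, in 32 peaks, and CCGTAAAG was in 30, GCCGCAAA in 18 and GTCGTAAA in 18. None of these occurred in the side windows, which the ranking favoured. The element GYCGYAAA, where Y is C or T, covers GCCGTAAA, GCCGCAAA, GTCGTAAA and GTCGCAAA (12 peaks). CCGTAAAG, CCGGAAAG (13 peaks) and GCCGGAAA (12 peaks) also ranked high and are not covered by it. CCGTAAAG shares CCGTAAA with GCCGTAAA, and CCGGAAAG shares CCGGAAA with GCCGGAAA, so such overlapping words can count the same stretch. The element lay in 64 of 98 shared peaks (65.3%, exact 95% interval 55.0 to 74.6) and in 22 of the 25 with the highest untreated score. Peaks at CHEK1, DLAT, MPC1, DNAJC19, TOMM7, RAD52, TTI2 and E4F1 itself held it, and those at MRFAP1, NARFL and ZNF862 were the exceptions among the first 25. It was not in the shared peaks at MRPL16, MRPL21, MRPL40, MRPL44, NDUFS3 and RPS7.

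The element was also present in peaks that had no part in its choice. It lay in 24 of the 157 gemcitabine-specific peaks (15.3%, exact 95% interval 10.0 to 21.9) and in 0 of the windows on either side (exact McNemar p = 1.19e-07 on each side). GOLGA7, NDUFS5, NAA30, CWF19L2, IPO8, KIF1BP, NOL6 and HAX1 were among them. On the main chromosomes, gemcitabine-specific peaks with the element had a median score of 79 against 51 without it (permutation p = 1e-05, the smallest value the permutations allow). Only 0.575% of 13228 unbound CpG-rich promoters (76 of them) held it within 50 bp of the TSS, below the lower bound of 10.0% in gemcitabine-specific peaks, a bound chosen after the values were seen. What binds the element was not tested.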
